A study of Mus musculus with 21 samples.

How the data were processed

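RNA from whole mouse knee joints was measured on 21 Affymetrix Mouse Gene 1.0 ST arrays, 1 per sample. Groups were taken from the sample titles: naive knees, and sham and DMM knees at 6 h, 3 days and 7 days, 3 arrays each. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes; the version is not given in the sources used here. They ran from 0.66 to 13.99, with array medians from 4.35 to 4.51, and were used as deposited. With no scanner files analysed here, background correction was not repeated and signal over background was not known per probe set.

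The value table held 35556 probe sets. Of these, 21789 had exactly 1 gene symbol, 1621 had several and 12146 were not in the annotation used here. Probe sets with 1 symbol were tested, and for the 999 genes with several, the probe set with the highest mean over all arrays was kept, which left 19938 genes. Probe sets without exactly 1 symbol were left out of the comparisons and tested separately.

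Tests used R 4.3.3 and limma 3.58.1. A linear model with 1 mean per group was fitted to all 21 arrays (lmFit, 14 residual degrees of freedom), followed by empirical Bayes moderation of the variances (eBayes) and 15 contrasts: DMM against sham at each time and averaged over times, sham and DMM against naive at each time, the difference of the DMM effect between each pair of times, and operated knees of neighbouring times. P-values were adjusted by the Benjamini-Hochberg method over all genes within each contrast, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are limma's moderated ones. The 29 gene lists, of cell type markers and processes, had 520 members, of which 479 were measured. Lists were tested with camera at a preset correlation of 0.01 and adjusted over 435 tests, and the adjusted p with a correlation estimated for each list is given beside it. A list's score on an array is the mean difference of its members from the naive group. For the count "adjusted over the list alone", the adjustment covered the list's members in that contrast.

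The groups, contrasts, thresholds, gene lists, alternatives and the rule for naming genes were set before the data were examined. By that rule up to 8 rises and 8 falls of largest log2 change were open to naming in each comparison, among called genes whose arrays did not overlap between the groups, together with up to 4 called members of each list (smallest p first) or 1 member of a list that passed without any called member, and every member of the osteoarthritis panel in DMM against sham. Where fewer than 5 genes were called, the 5 rises and 5 falls of smallest p were open to naming as values that did not pass. Predicted genes and multigene families of receptors were left out of the first part of the rule, and some open names were left out to save room.

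The model was tested on simulated data first. For DMM against sham at 7 days, 32.8% of genes simulated with a log2 change of 0.5, 95.5% of those with 1 and 100% of those with 2 were called with the right sign, and 3.8% of calls were unchanged genes. With no change simulated, that contrast gave 0 calls, and operated knees of 7 against 3 days gave 1. The simulated genes varied independently of each other, and no simulated array stood apart. These rates may therefore be more favourable than those on the real arrays. Agreement between DMM and sham responses was set against 100 simulations in which unchanged groups were compared with the same simulated naive arrays. All simulated groups had the same spread for each gene.

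Alternatives were leaving out the 25% of genes with the lowest mean, averaging probe sets, quantile normalization applied again, subtracting array medians, limma-trend with robust moderation, array weights, the replicate number as a block, fitting only the groups compared, requiring a 2-fold change, and leaving out each array in turn. For lists they were an estimated correlation, the fry test, the block and the medians. An interquartile range covariate, and leaving out 4 arrays together, were added after seeing the data.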

Results

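Transcripts were measured in whole right knee joints of male C57B/6 mice aged 10 weeks, from which skin and most of the muscle had been removed. Destabilisation of the medial meniscus (DMM), an operation that frees the medial meniscus and is used as a model of osteoarthritis, was set against a sham operation in which only the joint capsule was opened. Operated knees were collected 6 h, 3 days or 7 days after surgery, and naive knees came from mice that received 15 min of anaesthesia and no operation. The 7 groups (naive, and sham and DMM at each time) had 3 arrays each, 21 in all, which the design text calls biological replicates. Each array gave log2 expression values for 19938 genes. The array medians, taken over all 35556 probe sets, lay between 4.35 and 4.51. Signal over background was not known, so where a group mean lay under these medians, as in naive knees for Arg1 (3.56), Saa3 (3.88), Cxcl5 (3.90) and Mmp12 (3.86), the differences given below may be lower bounds. The number of arrays limits the precision of every comparison. A gene is said to have risen or fallen where limma's adjusted p was under 0.05 over all genes.

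One sham array stood apart from its group. Taken as differences from the naive mean across genes, which are not independent replicates, the profile of sham 6 h replicate 1 had a mean r of 0.087 with the other sham 6 h arrays, 0.462 with the sham 3 d and sham 7 d arrays, 0.449 with the DMM 3 d arrays and 0.438 with the DMM 7 d arrays. Its best correlation with another group exceeded that with its own by 0.376, and the largest such gap among the other operated arrays was 0.083. All profiles share the same naive mean, which raises each r by construction, and no value for unchanged arrays was simulated. Genes induced by glucocorticoids, hormones released under stress, showed the same split, since their mean score relative to naive knees was -0.556 in replicate 1, 0.971 in replicate 2 and 0.941 in replicate 3. The sham 3 d arrays had a mean score of -0.421 ± 0.059 (SD, n = 3) on that list.

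The main question was which transcripts differed between DMM and sham knees at the same time after surgery. At 6 h, DMM knees carried more transcripts of chemokines and of the osteoarthritis panel, 2 of the gene lists. The largest rises were in Arg1, an arginase made by macrophages in healing tissue, and Ankrd1, a cofactor induced in strained muscle. The monocyte-attracting chemokines Ccl2 and Ccl7 rose, as did the acute-phase protein Saa3, the metalloproteinase inhibitor Timp1 and Prg4, which encodes the joint lubricant lubricin. Igll1 and Pax5, genes of immature B cells, fell. In all, 202 genes rose and 132 fell, of which 58 and 28 changed at least 2-fold.

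Arg1 was higher by 3.62 on the log2 scale (SE 0.48, adjusted p = 0.000234), at 7.67 ± 1.46 in DMM and 4.05 ± 0.18 in sham knees (SD, n = 3). Ankrd1 was higher by 3.61 (SE 0.36, adjusted p = 4.82e-06), Ccl2 by 2.50 (SE 0.18, adjusted p = 7.36e-08), Saa3 by 2.63 (SE 0.46, adjusted p = 0.00289) and the small heat shock protein Hspb1 by 2.14 (SE 0.23, adjusted p = 7.88e-06). Of 23 chemokines measured, 8 rose and 15 did not pass, and 11 rose when adjusted over the list alone (list adjusted p = 3.55e-12, and adjusted p = 0.00359 with an estimated correlation). They included Ccl7 (2.27), Cxcl14 (1.64) and Cxcl3 (1.44). The osteoarthritis panel, 15 measured genes often assayed in this model, moved up, with 8 rises over all genes and 10 rises and 1 fall adjusted over the list alone (list adjusted p = 3.55e-12, and adjusted p = 0.00635 with an estimated correlation). Its risers included Timp1 (1.85), Mmp3 (1.71) and Inhba (1.16). Each measured panel gene is also in another list, such as Ccl2 in chemokines, so the panel is not separate evidence. Il1b (1.10, adjusted p = 0.0848), Adamts4 (0.68, adjusted p = 0.0838), Il6 (0.35, adjusted p = 0.77), Adamts5 (-0.24, adjusted p = 0.664) and Mmp13 (-0.45, adjusted p = 0.313) did not pass, nor did the cartilage matrix genes Acan (-0.28, adjusted p = 0.625) and Col2a1 (0.01, adjusted p = 0.995).

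Of 22 inflammatory mediators, 6 rose, and 11 when adjusted over the list alone (list adjusted p = 2.76e-08, but adjusted p = 0.0901 with an estimated correlation). Of 15 genes for collagen processing and endoplasmic reticulum chaperones, 5 rose, among them Creld2 (1.21) and Hspa5 (0.84), and 7 rose and 1 fell when adjusted over the list alone (list adjusted p = 2.97e-05, but adjusted p = 0.409 with an estimated correlation). Of 13 synovial fibroblast genes, Prg4 (1.23), Pdpn (1.67) and Has1 (1.00), the last a hyaluronan synthase, rose and 2 fell, and the list as a whole did not pass (list adjusted p = 0.151). Of 24 macrophage and monocyte genes, Arg1, the scavenger receptor Msr1 (1.33) and the Fc receptor Fcgr1 (0.99) rose (list adjusted p = 0.000566, but adjusted p = 0.471 with an estimated correlation). Of 12 B lineage genes, 5 fell and 9 fell when adjusted over the list alone (list adjusted p = 1.77e-12, but adjusted p = 0.062 with an estimated correlation). Igll1, a part of the pre-B cell receptor, fell by 1.20 (SE 0.22, adjusted p = 0.00574), and the B cell transcription factor Pax5 fell by 0.86 (SE 0.16, adjusted p = 0.00569). The lowest B lineage score, -0.919, was in DMM 6 h replicate 2, the DMM 6 h array with the narrowest interquartile range of values (3.21), and the scores of replicates 1 and 3 were -0.638 and -0.497. The erythroid list was lower too, with 0 of 11 genes passing over all genes and 4 adjusted over the list alone (list adjusted p = 5.12e-06, but adjusted p = 0.369 with an estimated correlation).

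The DMM and sham arrays at 6 h did not overlap for 13.5% of all genes, against 10% by chance. They did not overlap for any gene named as having risen or fallen either, but the naming rule fixed this in advance for the largest rises and falls. Without sham 6 h replicate 1, 313 genes passed, 215 of them among the 334, and the largest fall, Sfrp2, a Wnt modulator (-1.81, adjusted p = 0.0202), no longer passed; it did not pass without DMM replicate 1 or 2 either. The count was 206 without sham replicate 2, 193 without sham replicate 3, 170 without DMM replicate 2, 600 without DMM replicate 3, and 66 when the spread was taken from these 6 arrays alone. Mmp3 did not pass without sham replicate 2 or 3. Of the 51 called genes open to naming by the rule, 24 passed with each of the 6 arrays left out, among them Arg1, Ankrd1, Ccl2 and Igll1.

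At 3 days, the largest fall in DMM against sham knees was in Col10a1, a cartilage gene, and 7 of 24 cartilage genes fell (list adjusted p = 4.66e-18, but adjusted p = 0.0626 with an estimated correlation). The list for osteoblasts and osteocytes moved the same way, with no gene passing (adjusted p = 0.0883 with an estimated correlation). Col10a1 encodes the collagen of hypertrophic cartilage, and Col2a1, the main collagen of cartilage, Hapln1, which links hyaluronan to aggrecan, and Matn3, a cartilage matrix protein, fell as well. Ankrd1, Timp1 and Lox, an enzyme that crosslinks collagen, rose. In all, 16 genes rose and 24 fell, or 14 and 14 after quantile normalization applied again.

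Col10a1 fell by 2.17 (SE 0.27, adjusted p = 0.00118), from 8.44 ± 0.14 in sham to 6.27 ± 0.22 in DMM knees (SD, n = 3), and Col2a1 fell by 1.5 (SE 0.22, adjusted p = 0.00978). Of 24 cartilage matrix and chondrocyte genes, 7 fell and 17 did not pass, while 17 fell and 1 rose when adjusted over the list alone (list adjusted p = 4.66e-18, but adjusted p = 0.0626 with an estimated correlation). The list moved together with that for osteoblasts and osteocytes, of whose 9 genes none passed and 7 fell when adjusted over the list alone (list adjusted p = 7.54e-09, but adjusted p = 0.0883 with an estimated correlation). B lineage genes were again lower, with Cd79a passing (a log2 change of -1.0, adjusted p = 0.0304) and 9 of 12 falling when adjusted over the list alone (list adjusted p = 1.66e-10, but adjusted p = 0.0801 with an estimated correlation). Erythroid genes were lower beside them, 0 of 11 over all genes and 9 adjusted over the list alone (list adjusted p = 4.01e-08, but adjusted p = 0.261 with an estimated correlation). Timp1 was higher by 1.39 (SE 0.24, adjusted p = 0.0229) and Ankrd1 by 1.92 (SE 0.36, adjusted p = 0.0256). Of the 15 panel genes, Timp1 rose, Col2a1 fell and the others did not pass, among them Arg1 (1.52, adjusted p = 0.209), Mmp3 (1.29, adjusted p = 0.126) and Ccl2 (0.59, adjusted p = 0.197). The chemokine list did not pass (list adjusted p = 0.39).

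At 3 days the arrays of the groups did not overlap for 16.2% of all genes, against 10% by chance. They did not overlap for any gene named as having risen or fallen either, which the naming rule again fixed for the largest changes. The count of 40 fell to 1 without sham 3 d replicate 1, 5 without sham replicate 2, 2 without sham replicate 3, 12 without DMM replicate 2 and 2 without DMM replicate 3, rose to 503 without DMM replicate 1, and was 3 when the spread was taken from these 6 arrays alone. Of the 22 called genes open to naming by the rule, Col10a1 was the 1 that passed with each of the 6 arrays left out.

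At 7 days, most differences between DMM and sham knees were falls, with 14 of 24 cartilage genes among them. Col10a1, Matn3, Hapln1, Col2a1 and the aggrecan gene Acan fell, and so did Actc1, a muscle actin, and Myl1, a myosin light chain. The rises included Arg1, Ms4a6d, the inducible nitric oxide synthase Nos2, the chemokine receptor Ccr2 and Egln3, a prolyl hydroxylase induced by low oxygen. In all, 48 genes rose and 123 fell.

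Col10a1 fell by 2.57 (SE 0.27, adjusted p = 6.41e-05), from 8.76 ± 0.24 in sham to 6.19 ± 0.56 in DMM knees (SD, n = 3). Matn3 fell by 2.13 (SE 0.32, adjusted p = 0.00222), Col2a1 by 1.62 (SE 0.22, adjusted p = 0.000972) and Acan by 0.98 (SE 0.21, adjusted p = 0.0262). Of 24 cartilage genes, 14 fell, 1 rose and 9 did not pass, and 18 fell and 1 rose when adjusted over the list alone (list adjusted p = 6.04e-28, and adjusted p = 0.0281 with an estimated correlation). Of 9 osteoblast and osteocyte genes, 2 fell, the alkaline phosphatase Alpl (-0.93) and Ifitm5 (-0.81), and 7 fell when adjusted over the list alone (list adjusted p = 2.67e-10, but adjusted p = 0.0718 with an estimated correlation). Of 24 macrophage and monocyte genes, 4 rose, and 8 when adjusted over the list alone (list adjusted p = 3.54e-11, but adjusted p = 0.13 with an estimated correlation). Arg1 was higher by 2.62 (SE 0.48, adjusted p = 0.0107) and Ccr2 by 0.75 (SE 0.13, adjusted p = 0.00557). Ms4a6d was higher by 1.35 (SE 0.20, adjusted p = 0.00222) and Egln3 by 1.28 (SE 0.18, adjusted p = 0.00102). Of 23 chemokines, 4 rose, Ccl2 (0.89), Cxcl14 (0.77), Ccl9 (0.76) and Cxcl16 (0.90), and adjusted over the list alone 7 rose and 1 fell (list adjusted p = 8.81e-05, but adjusted p = 0.062 with an estimated correlation). Of 24 skeletal muscle genes, Myl1 (-1.15) and Pvalb (-0.91) fell (list adjusted p = 6.79e-06, but adjusted p = 0.447 with an estimated correlation).

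The arrays at 7 days did not overlap for 16.2% of all genes, against 10% by chance. They did not overlap for any gene named as having risen or fallen either, which the naming rule again fixed for the largest changes. The count of 171 fell to 41, 84 and 48 without sham 7 d replicates 1, 2 and 3 and to 59, 67 and 43 without DMM replicates 1, 2 and 3. Arg1 did not pass without sham replicate 1 or DMM replicate 2, and 12 of the 40 called genes open to naming, such as Col10a1, Matn3, Col2a1 and Ccr2, passed with each of the 6 arrays left out.

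**Figure D1:**
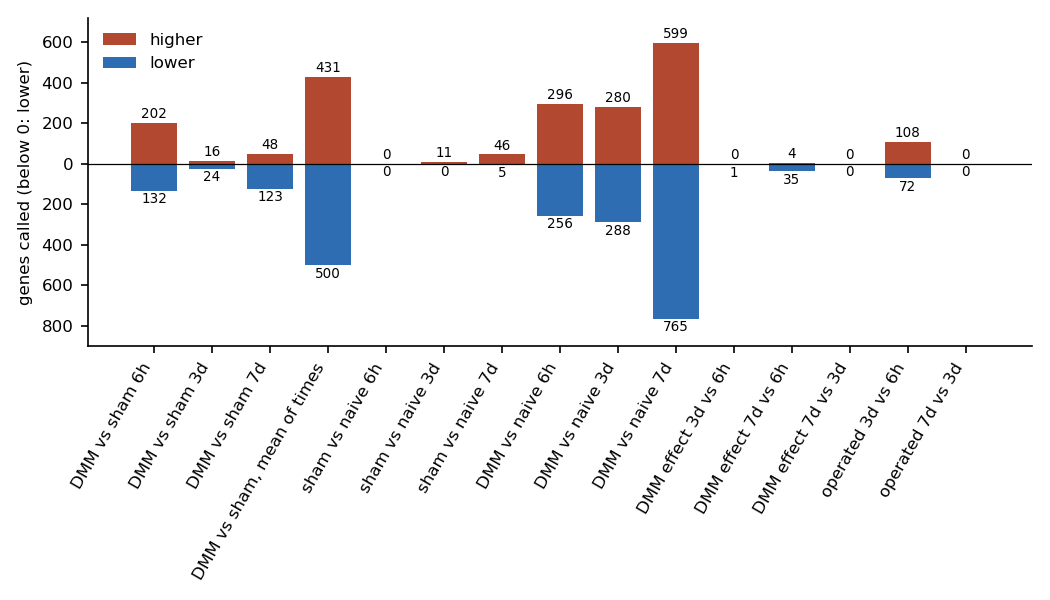
Number of genes that rose (upward bars) or fell (downward bars) in each of the 15 comparisons, at limma adjusted p under 0.05 over 19938 genes. DMM against naive knees at 7 days gave the most (599 higher and 765 lower, or 713 and 629 after quantile normalization applied again), and 3 comparisons gave 0.

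Averaged over the 3 times, with 9 DMM against 9 sham arrays, 431 genes rose and 500 fell. Arg1 (2.59, SE 0.28, adjusted p = 7.49e-06), Ankrd1 (2.36, SE 0.21, adjusted p = 8.11e-07), Timp1 (1.39, SE 0.14, adjusted p = 2.73e-06) and Ccl2 (1.32, SE 0.11, adjusted p = 3.81e-07) were among the rises. Col10a1 fell furthest (-1.63, SE 0.16, adjusted p = 2.11e-06), and Retnla, a product of alternatively activated macrophages and fat (-1.51, SE 0.17, adjusted p = 1.75e-05), Hapln1 (-1.36) and Matn3 (-1.29) fell as well. The average for Col10a1 joins falls at 3 and 7 days (-2.17 and -2.57) with 6 h, where it was not called. At 6 h its values ran from 7.9 to 8.78 in DMM and 7.79 to 9.02 in sham knees. Col2a1 differed by 0.01 at 6 h. Of 15 panel genes, 10 rose, 3 fell and 2 did not pass. The aggrecanase Adamts4 rose (0.65, SE 0.11, adjusted p = 0.00129), the aggrecanase Adamts5 did not pass (0.02, SE 0.11, adjusted p = 0.949), and the collagenase Mmp13 fell (-0.61, SE 0.11, adjusted p = 0.0019). Il6 did not pass (0.54, SE 0.22, adjusted p = 0.174), while Il1b rose by 0.74 (SE 0.18, adjusted p = 0.0198). Adamts4, Mmp13 and Il1b passed in this average but at none of the 3 times alone. At 6 h, 3 days and 7 days Mmp13 changed by -0.45, -0.84 and -0.55, and Il1b by 1.10, 0.20 and 0.92.

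Among the lists, 4 passed both ways in the averaged comparison. They are not independent, since the panel shares Ccl2 with chemokines, and Acan and Col2a1 with the cartilage list. The osteoarthritis panel (list adjusted p = 2.3e-08, and adjusted p = 0.0266 with an estimated correlation) and chemokines (9 of 23 rose and 1 fell, list adjusted p = 1.06e-07, and adjusted p = 0.0181 with an estimated correlation) moved up. The cartilage list (18 of 24 fell and 1 rose, list adjusted p = 1.54e-21, and adjusted p = 0.0468 with an estimated correlation) and the B lineage list (8 of 12 fell, list adjusted p = 1.14e-14, and adjusted p = 0.0443 with an estimated correlation) moved down. Adjusted over each list alone, the panel held 11 rises and 3 falls, chemokines 10 and 2, cartilage 2 and 21, and the B lineage 0 and 11. The 1 cartilage gene that rose was Prg4 (0.74, SE 0.07, adjusted p = 2.73e-06), which synovial cells also make. Vpreb3 (-0.96, SE 0.13, adjusted p = 9.5e-05) and Igll1 (-0.91, SE 0.13, adjusted p = 0.000167), genes of B cell precursors, fell. Of 11 erythroid genes, 4 fell alongside, and 10 adjusted over the list alone (list adjusted p = 2.26e-08, but adjusted p = 0.253 with an estimated correlation). Bone genes also fell, with 6 of 9 osteoblast and osteocyte genes lower, such as Dmp1 (-1.15) and Phex (-0.78), and 8 adjusted over the list alone (list adjusted p = 1.54e-09, but adjusted p = 0.0801 with an estimated correlation). Of 13 osteoclast genes, 6 fell, among them Acp5 (-0.52) and Ctsk (-0.54), and 8 adjusted over the list alone (list adjusted p = 3.03e-07, but adjusted p = 0.13 with an estimated correlation). Without DMM 3 d replicate 1, 1456 genes passed in place of 931, and with at least a 2-fold change required, 34 did.

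**Figure D2:**
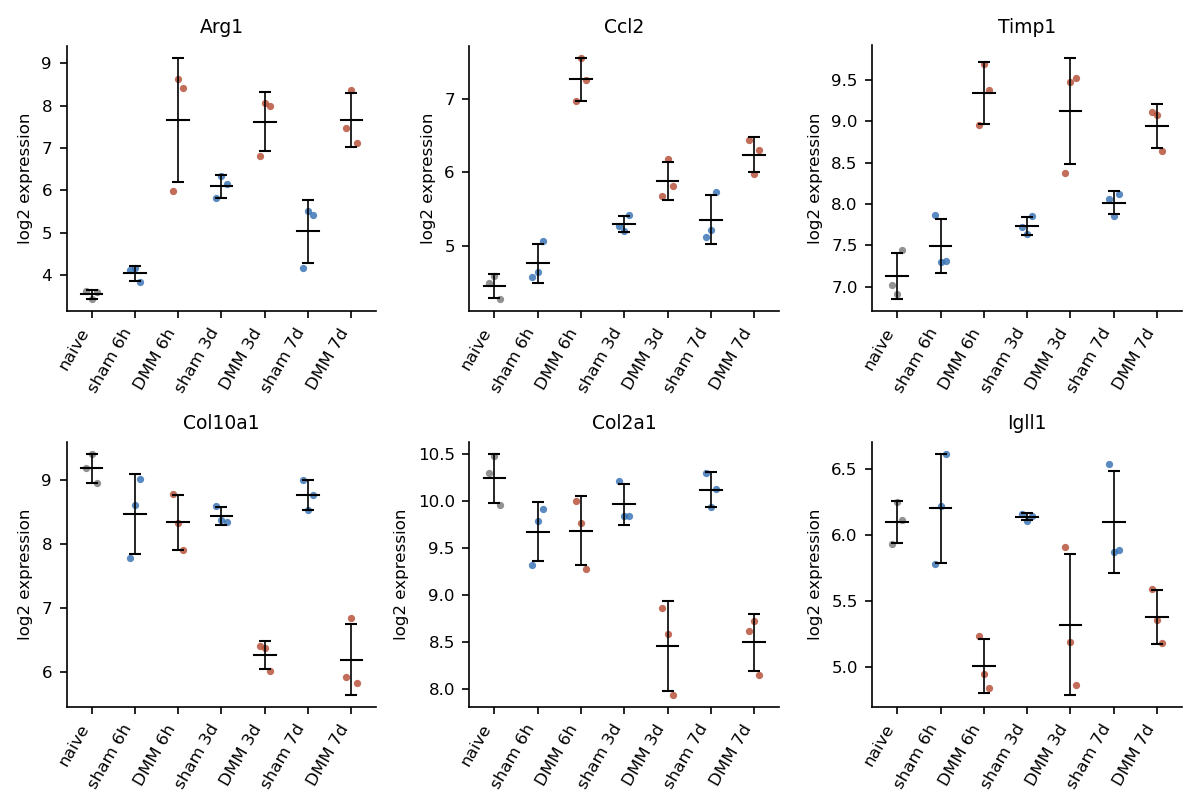
Log2 expression of 6 genes on each array (points) with the mean and SD of each group (line and bar, n = 3 arrays). Arg1 averaged 4.05 in sham and 7.67 in DMM knees at 6 h, and Col10a1 averaged 8.76 in sham and 6.19 in DMM knees at 7 days.

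Whether the DMM effect itself differed between times was tested as an interaction. From 6 h to 3 days it became smaller for Ccl2 alone (-1.91, SE 0.26, adjusted p = 0.00446), the 1 gene that passed. As a list, chemokines dropped (9 of 23 adjusted over the list alone, list adjusted p = 2.51e-11, and adjusted p = 0.00359 with an estimated correlation), and so did the osteoarthritis panel (3 of 15 adjusted over the list alone, list adjusted p = 1.19e-06, and adjusted p = 0.0443 with an estimated correlation). From 6 h to 7 days the DMM effect was lower for 35 genes and higher for 4. Among them were cartilage genes, Col10a1 (-2.44, SE 0.38, adjusted p = 0.0113) and Col2a1 (-1.63, SE 0.31, adjusted p = 0.0345), the chemokines Ccl2 (-1.61, SE 0.26, adjusted p = 0.0114) and Ccl7 (-1.63, SE 0.28, adjusted p = 0.0172), and Hspb1 (-1.90, SE 0.32, adjusted p = 0.0172). The muscle genes Myl1 (-1.14), Asb5 (-1.38) and Cox7a1 (-1.64) were also lower, and Aoah, which inactivates bacterial lipopolysaccharide, was higher (1.43). Adjusted over the cartilage list alone, 15 of 24 genes passed as lower (list adjusted p = 1.81e-14, but adjusted p = 0.0871 with an estimated correlation). The osteoblast and osteocyte list moved the same way, with 0 of 9 genes passing over all genes and 2 as lower adjusted over the list alone (list adjusted p = 0.000142, but adjusted p = 0.265 with an estimated correlation). From 3 to 7 days limma called 0 genes, with 1134 at an unadjusted p under 0.05 and a smallest adjusted p of 0.824.

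These interaction counts moved with individual arrays. The count of 39 became 5 and 20 without sham 6 h replicates 2 and 3, 13 and 217 without DMM 6 h replicates 2 and 3, 18, 15 and 0 without sham 7 d replicates 1, 2 and 3, 18 and 11 without DMM 7 d replicates 1 and 3, and 0 when the spread was taken from the 12 arrays compared. None of the 12 called genes open to naming passed in every one of these fits; Col10a1 and Hspb1 lost their call without sham 7 d replicate 3, and Ccl2 without that array or sham 6 h replicate 2. The count of 1 (Ccl2) became 14 without DMM 3 d replicate 1, 7, 2 and 4 without DMM 6 h replicates 1, 2 and 3, 2 and 6 without sham 6 h replicates 1 and 3, and 2 without sham 3 d replicate 1 or DMM 3 d replicate 2 or 3, and Ccl2 passed in each of these fits. The count of 0 between 3 and 7 days became 1 without DMM 3 d replicate 2.

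Genes called at more than 1 time were counted for each direction. Between 6 h and 3 days 9 rises and 5 falls were shared, against 0.162 and 0.159 for independent lists. Between 6 h and 7 days 15 rises and 12 falls were shared, against 0.486 and 0.814, and between 3 and 7 days 3 rises and 17 falls, against 0.0385 and 0.148. Ankrd1 was among the genes called higher, and Retnla among those called lower, at all 3 times. At 3 days neither call held with every array left out in turn. At 6 h Retnla did not pass without sham 6 h replicate 1, DMM 6 h replicate 1 or DMM 6 h replicate 2. The lists of the 3 times share each gene's estimate of spread, so they are not fully independent. The 17 shared falls of 3 and 7 days included Col10a1, Col2a1, Hapln1, Matn3, Col11a1 and Col9a1, all of them cartilage genes.

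The next question was how far surgery without destabilisation changed the joint, from sham against naive knees. At 6 h no gene passed with limma, and 1014 had an unadjusted p under 0.05, with a smallest adjusted p of 0.107. The smallest p among non-overlapping rises belonged to Ptx3 (1.23, SE 0.21, adjusted p = 0.107) and the chemokine Cxcl3 (0.94, SE 0.16, adjusted p = 0.107), and these values did not pass. The chemokine list was nonetheless higher (0 of 23 over all genes, 7 adjusted over the list alone, list adjusted p = 5.79e-12, and adjusted p = 0.00359 with an estimated correlation). Leaving out sham 6 h replicate 1, the array that stood apart, let 19 genes pass.

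At 3 days, 11 genes rose in sham against naive knees and none fell. They included Fcgr1 (1.17, SE 0.17, adjusted p = 0.00384) and the lysosomal protease Ctss (1.03, SE 0.14, adjusted p = 0.00384), both made by macrophages, Dpep2, a dipeptidase (1.32, SE 0.15, adjusted p = 0.000233), and the neutrophil-attracting chemokine Cxcl5 (1.94, SE 0.35, adjusted p = 0.0336). Of 24 macrophage and monocyte genes, 2 rose, and 16 when adjusted over the list alone (list adjusted p = 6.48e-31, and adjusted p = 0.0197 with an estimated correlation). Chemokines (2 of 23, and 14 adjusted over the list alone, list adjusted p = 2.31e-19, and adjusted p = 0.000596 with an estimated correlation) and interferon-induced genes (0 of 14, and 7 adjusted over the list alone, list adjusted p = 2.06e-16, and adjusted p = 0.0289 with an estimated correlation) were higher too. The count of 11 was 5, 3 and 6 without naive replicates 1, 2 and 3 and 6, 5 and 5 without sham replicates 1, 2 and 3, and 90 when the spread was taken from the 6 arrays compared. Of the 8 called genes open to naming, Dpep2, Fcgr1 and Ctss passed with each of the 6 arrays left out.

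At 7 days, 46 genes rose and 5 fell in sham knees. Stromelysin, Mmp3 (2.67, SE 0.33, adjusted p = 0.00133), the macrophage elastase Mmp12 (2.66, SE 0.40, adjusted p = 0.00416), Saa3 (2.71, SE 0.46, adjusted p = 0.0138) and the chemokine Ccl8 (2.46, SE 0.44, adjusted p = 0.0183) rose most. Genes of scar and repair matrix were higher, with 5 of 22 rising, among them Col3a1 (1.18) and Col6a3 (0.96), and 14 when adjusted over the list alone (list adjusted p = 4.53e-12, but adjusted p = 0.114 with an estimated correlation). Chemokines (7 of 23, and 10 adjusted over the list alone, list adjusted p = 3.33e-11, and adjusted p = 0.00359 with an estimated correlation), the osteoarthritis panel (4 of 15, and 8 adjusted over the list alone, list adjusted p = 3.95e-07, and adjusted p = 0.0364 with an estimated correlation) and matrix proteases (3 of 25, and 11 adjusted over the list alone, list adjusted p = 5.15e-06, and adjusted p = 0.0294 with an estimated correlation) moved up. The count of 51 was 10, 3 and 23 without naive replicates 1, 2 and 3, 15 and 6 without sham replicates 2 and 3, and 107 when the spread was taken from the 6 arrays compared. Of the 28 called genes open to naming, 3 passed with each of the 6 arrays left out, Mmp3 among them.

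DMM against naive knees gave the response to the whole operation. At 6 h 296 genes rose and 256 fell, at 3 days 280 rose and 288 fell, and at 7 days 599 rose and 765 fell. The larger direction turned with the scaling, to 286 higher and 287 lower at 6 h with array medians subtracted, and to 379 and 260 at 3 days and 713 and 629 at 7 days after quantile normalization applied again. Arg1 was higher by 4.11, 4.06 and 4.10 at the 3 times (SE 0.48 each, adjusted p = 2.38e-05, 6.05e-05 and 2.94e-05). Saa3 (3.80, 2.76 and 4.07), Mmp3 (3.38, 2.70 and 3.35), the hyaluronan-binding protein Tnfaip6 (3.05, 2.46 and 2.17) and Cxcl5 (3.04, 2.81 and 3.26) rose at every time. Col10a1 was lower by -2.92 at 3 days (SE 0.27, adjusted p = 3.64e-06) and -2.99 at 7 days (SE 0.27, adjusted p = 1.67e-06). The metallothioneins Mt1 (1.77, adjusted p = 0.00199) and Mt2 (2.42, adjusted p = 0.00899), which bind metals and respond to glucocorticoids, rose at 6 h, and Mt2 did not pass without naive replicate 3.

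Cartilage genes fell in DMM against naive knees in 6 of 24 cases at 6 h, 16 at 3 days and 18 at 7 days, with 1 rise at each time, and 16, 19 and 20 fell when adjusted over the list alone (list adjusted p = 2.17e-09, 7.38e-25 and 8.79e-23, and adjusted p = 0.173, 0.0344 and 0.0424 with an estimated correlation). Chemokines rose in 13, 9 and 12 of 23 cases, and 14, 13 and 16 when adjusted over the list alone (list adjusted p = 1.16e-19, 1e-09 and 1.32e-13, and adjusted p = 0.000596, 0.00635 and 0.0032 with an estimated correlation). Osteoblast and osteocyte genes fell in 8 of 9 cases at 3 days, such as Dmp1 (-2.35) and Phex (-1.88), and 9 when adjusted over the list alone (list adjusted p = 1.38e-14, and adjusted p = 0.0364 with an estimated correlation). Macrophage and monocyte genes rose in 15 of 24 cases at 7 days, and 18 when adjusted over the list alone (list adjusted p = 2.06e-16, but adjusted p = 0.0718 with an estimated correlation). Interferon-induced genes rose in 8 of 14 cases at 7 days, with Ifit1 at 1.46, and 12 when adjusted over the list alone (list adjusted p = 1.84e-09, but adjusted p = 0.0801 with an estimated correlation). The arrays of the compared groups did not overlap for 19.6%, 20.4% and 30.0% of genes, against 10% by chance.

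The counts of DMM against naive knees also moved with individual arrays. The 552 genes of 6 h became 289, 271 and 322 without naive replicates 1, 2 and 3, and 290 and 1531 without DMM replicates 2 and 3. The 568 genes of 3 days became 272, 182 and 336 without naive replicates 1, 2 and 3, and 1609, 216 and 173 without DMM replicates 1, 2 and 3. The 1364 genes of 7 days became 759 and 663 without naive replicates 1 and 2, and 817 and 819 without DMM replicates 1 and 3. Arg1 at each time, and Col10a1 at 3 and 7 days, passed in each of these fits, as did 47 of 70, 45 of 81 and 71 of 95 called genes open to naming at the 3 times.

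**Figure D3:**
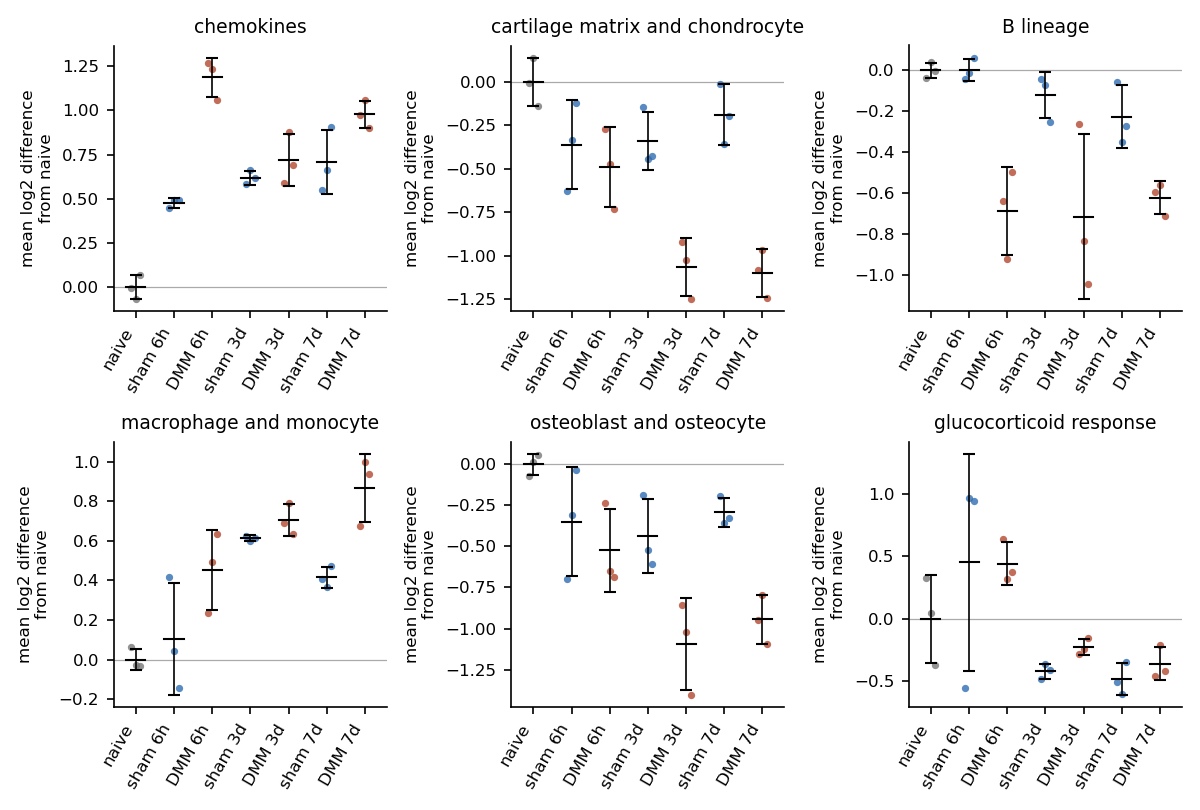
Mean log2 difference from the naive group over the members of 6 gene lists, on each array (points) with the mean and SD of each group (line and bar, n = 3 arrays). The B lineage score averaged 0.002 in sham and -0.685 in DMM knees at 6 h, and the glucocorticoid score of sham 6 h replicate 1 was -0.556 against 0.971 and 0.941 for replicates 2 and 3.

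The DMM and sham responses were set side by side as log2 changes against the same naive arrays, across genes. Pearson's r was 0.516 at 6 h, 0.590 at 3 days and 0.714 at 7 days. Groups simulated without any effect, sharing simulated naive arrays, gave 0.501, 0.50 and 0.499. Spearman's rho was 0.501, 0.50 and 0.689, against 0.479, 0.477 and 0.478 in the simulation. Equal spread in all simulated groups fixes the simulated r near 0.50 by construction. The real log2 changes varied unequally, with a variance of 0.0739 for DMM and 0.0269 for sham at 6 h. The simulated r and rho are therefore no baseline for the real ones. The covariance was 0.023, 0.0268 and 0.0471, at each time above the simulated covariance of 0.0115, 0.0115 and 0.0114. Both responses called 10 genes higher at 3 days, against 0.154 for independent lists, and 38 higher and 2 lower at 7 days, against 1.38 and 0.192. The 3 naive arrays cannot be divided into parts of at least 2 arrays, so part of this excess may come from the shared controls.

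The last question was what changed with time in the mean of sham and DMM knees, where a call does not show a change after both operations. From 6 h to 3 days 108 genes rose and 72 fell. Rises were seen in Mmp12 (1.59, SE 0.28, adjusted p = 0.00746), Ctss (0.71, SE 0.10, adjusted p = 0.00349) and the interferon-induced genes Ifit3 (0.93, SE 0.15, adjusted p = 0.00378) and Ifit1 (0.80, SE 0.14, adjusted p = 0.00608). The cytokine signalling inhibitor Socs3 fell (-0.84, SE 0.13, adjusted p = 0.00378), and so did the immediate early genes Dusp1 (-0.75, SE 0.12, adjusted p = 0.00429) and Fos (-0.82, SE 0.16, adjusted p = 0.0133), as well as Mt1 (-1.46, SE 0.22, adjusted p = 0.00353) and Il6 (-1.13, SE 0.27, adjusted p = 0.047). Of 22 immediate early genes, 4 fell, and 5 when adjusted over the list alone (list adjusted p = 2.7e-08, and adjusted p = 0.0165 with an estimated correlation). Of 22 genes of fibrous matrix and repair, 6 rose, and 15 when adjusted over the list alone (list adjusted p = 1.29e-15, but adjusted p = 0.0718 with an estimated correlation). Of 11 glucocorticoid-induced genes, 4 fell, and 9 when adjusted over the list alone (list adjusted p = 1.33e-11, but adjusted p = 0.108 with an estimated correlation).

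The count of 180 between 6 h and 3 days rose to 634, with all 180 among them, without sham 6 h replicate 1, the array that stood apart, and to 331 without DMM 6 h replicate 3. It dropped to 58 and 56 without sham 6 h replicates 2 and 3, 56 and 115 without DMM 6 h replicates 1 and 2, 60, 70 and 98 without sham 3 d replicates 1, 2 and 3, 102 and 118 without DMM 3 d replicates 2 and 3, and 44 when the spread was taken from the 12 arrays compared. Of the 43 called genes open to naming, 18 passed with each of the 12 arrays left out, among them Mmp12, Ifit3, Socs3 and Mt1 but not Fos or Il6. From 3 to 7 days limma called 0 genes, with 1450 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0699. Without DMM 3 d replicate 3, 55 genes passed, without sham 7 d replicate 3 or DMM 7 d replicate 3, 2 did, and without DMM 3 d replicate 2 or DMM 7 d replicate 1 or 2, 1 did.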

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

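The 2 tests on sham 6 h replicate 1, and the form of the sample splits used for the DMM effect between times, were chosen after the results were seen. The DMM effect differed between times for some genes and lists. Between 6 h and 3 days 1 gene, Ccl2, passed the interaction test (-1.91), and the lists of chemokines (adjusted p = 0.00359 with an estimated correlation) and of the osteoarthritis panel (adjusted p = 0.0443 with an estimated correlation) moved down. Between 6 h and 7 days 39 genes passed, among them Col10a1 (-2.44), Col2a1 (-1.63), Ccl2 (-1.61), Ccl7 (-1.63), Hspb1 (-1.90), Myl1 (-1.14), Asb5 (-1.38), Cox7a1 (-1.64) and Aoah (1.43). Among 13767 probe sets without exactly 1 gene symbol, which the report does not use, 30 were called in DMM against sham knees at 6 h, 13 higher and 17 lower, with 0 by limma at 3 days (1065 at an unadjusted p under 0.05) and 0 at 7 days (1181).

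Cartilage genes were lower in DMM than in sham knees at 3 and 7 days, by a list mean of -0.82 ± 0.11 (SE). The width of each array's values does not account for this, since with the interquartile range as a covariate the mean was -0.82 ± 0.12, 99.7% of its size. A smaller share of growth plate and bone in the DMM samples stays open. With the osteoblast and osteocyte list as a covariate the cartilage mean shrank to -0.33 ± 0.09, which is 40.5% of its size, so that such a difference may account for the larger part. Loss of cartilage transcripts within the joint surface stays open too. Osteoblast genes could themselves respond to surgery, and no list here separates joint cartilage from growth plate. At 7 days Col10a1, the collagen of hypertrophic cartilage, fell more (-2.57) than Col2a1 (-1.62) or Acan (-0.98). Prg4, which synovial cells also make, rose (0.57). These single genes do not settle where the falls arose.

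Sham 6 h replicate 1 stood apart from replicates 2 and 3. Its interquartile range was 3.36, with 12 arrays lower and 8 higher, which argues against the width of its values as the cause. A sham knee of a later time under a 6 h label could explain it, since its mean correlation with sham 3 d or 7 d arrays (0.462) exceeded that with its own group by 0.376, and the next largest gap of any other operated array was 0.083. The likeness was not particular to sham knees, with 0.449 for DMM 3 d and 0.438 for DMM 7 d. Single genes did not point one way. Its Ccl2 was 4.58, beside 4.64 and 5.07 in replicates 2 and 3. That was below 5.20 to 5.42 in sham 3 d and 5.11 to 5.73 in sham 7 d. Its Arg1 was 4.14, between 3.85 and 4.17 in replicates 3 and 2. That was below 5.81 to 6.35 in sham 3 d but near the lowest sham 7 d array (4.18). Its Timp1 was 7.87, within 7.63 to 8.12 in later sham knees and above 7.29 and 7.31 in replicates 2 and 3. Its Col10a1 was 7.79, below 8.61 and 9.02 in replicates 2 and 3 and below 8.34 to 9.0 in later sham knees. An animal that responded unlike its group mates stays open, and the array was kept under its label.

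B lineage genes were lower in DMM than in sham knees over the 3 times, by a list mean of -0.56 ± 0.09 (SE). With the interquartile range as a covariate the mean was -0.51 ± 0.06 (91% of its size), and with the erythroid list as a covariate it was -0.36 ± 0.08 (65.1% of its size). The first value argues against the width of the arrays' values as the whole cause, although within groups the B lineage score followed that width (r = 0.79). The second value cannot decide on a smaller share of bone marrow. An erythroid score is an imperfect measure of that share, so the adjustment may remove too little. That score was itself lower in DMM knees, at -0.607, -0.649 and -0.498 against -0.099, -0.075 and -0.291 in sham knees at 6 h, 3 days and 7 days. A smaller share of marrow thus stays open. A fall in B cell precursors within the marrow stays open too, as a hypothesis found on these arrays that was not tested here.

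Other splits of the same arrays were fitted to see how often they gave as many calls. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Counting the real split, 1 of 10 gave as many calls for DMM against sham at 6 h (334, highest other 72), 3 days (40, highest other 0) and 7 days (171, highest other 0), for sham against naive at 3 days (11, highest other 0) and 7 days (51, highest other 0), and for DMM against naive at 6 h (552, highest other 1), 3 days (568, highest other 0) and 7 days (1364, highest other 0). For sham against naive at 6 h, where the real count was 0, all 10 did, which a count of 0 fixes in advance, and the highest other count was 16. For DMM against sham averaged over times 1 of 100 drawn splits gave as many (931, highest other 25), which makes chance unlikely at that share. For operated knees between 6 h and 3 days 3 of 100 gave as many (180, highest other 250). That share is under 0.05, but other splits reached or passed the real count, so chance is not excluded. Between 3 and 7 days 100 of 100 gave as many (0, highest other 5), which the count of 0 fixes in advance. These shares were not adjusted for the number of contrasts.

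For the difference of the DMM effect between times the splits were drawn in 2 ways, and the outcome depends on which is used. The first way exchanged surgery labels within each time, which turns the DMM effect itself into an apparent time difference. It gave as many calls in 12 of 100 splits for 3 days against 6 h (1, highest other 569) and 7 of 100 for 7 days against 6 h (39, highest other 61), and so excluded chance for neither. After that outcome was seen, it was replaced by splits of the values left once the mean effects of surgery and time were taken out. These gave 3 of 100 (1, highest other 1) and 3 of 100 (39, highest other 719). For 7 against 3 days, where the real count was 0, both ways gave 100 of 100 (highest other 14 and 214), which that count fixes in advance. By the second way both shares against 6 h lie under 0.05, but other splits matched or exceeded the real counts, so chance is not excluded. A method chosen after an unfavourable outcome also weighs less than one fixed in advance. A split with 719 calls where the real count is 39 points to a structure of the samples, which was not tested. A real difference of the DMM effect between times was left in the shuffled values and could also give such a split.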

How the results depend on the processing

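The fits with the interquartile range as a covariate and without 4 arrays (DMM 6 h replicate 2, DMM 3 d replicate 3, DMM 7 d replicate 1 and sham 6 h replicate 1) were chosen after seeing the data. Counts of called genes depended on the arrays more than on scaling or filters. With each array of a comparison left out in turn, the count ranged from 170 to 600 for DMM against sham at 6 h (334 with all arrays), 1 to 503 at 3 days (40), 41 to 84 at 7 days (171) and 633 to 1456 averaged over times (931). It ranged from 0 to 19 for sham against naive at 6 h (0), 3 to 6 at 3 days (11) and 3 to 34 at 7 days (51), and from 271 to 1531 for DMM against naive at 6 h (552), 173 to 1609 at 3 days (568) and 663 to 980 at 7 days (1364). For the DMM effect it ranged from 1 to 14 between 3 days and 6 h (1), 0 to 217 between 7 days and 6 h (39) and 0 to 1 between 7 and 3 days (0), and for operated knees from 56 to 634 between 3 days and 6 h (180) and 0 to 55 between 7 and 3 days (0). Fewer arrays account for part of the drops by construction; the cause of the rises was not tested.

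With array weights, which ran from 0.37 (DMM 6 h replicate 3) to 5.28 (DMM 6 h replicate 1), counts rose to 2192, 349 and 283 for DMM against sham at the 3 times and 1916 averaged, 35, 153 and 194 for sham against naive, 5091, 1639 and 2658 for DMM against naive, 182 and 726 for the DMM effect at 3 and 7 days against 6 h, and 1768 and 26 for operated knees; the cause was not tested. With the spread taken only from the groups compared, counts were 66 and 3 for DMM against sham at 6 h and 3 days, 90 and 107 for sham against naive at 3 and 7 days, 286 and 319 for DMM against naive at 6 h and 3 days, 0 for the DMM effect between 7 days and 6 h, and 44 for operated knees between 3 days and 6 h. Requiring a 2-fold change left, by construction, 86, 21, 30 and 34 genes for DMM against sham at the 3 times and averaged, 7 and 21 for sham against naive at 3 and 7 days, 122, 138 and 200 for DMM against naive, 20 for the DMM effect between 7 days and 6 h and 15 for operated knees between 3 days and 6 h.

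With the interquartile range as a covariate, counts were 1102, 11 and 342 for DMM against sham at the 3 times, 28 and 27 for sham against naive at 3 and 7 days, 1010 for DMM against naive at 6 h, 6 and 518 for the DMM effect at 3 and 7 days against 6 h, and 353 for operated knees between 3 days and 6 h; the cause was not tested. Without the 4 arrays, they were 7 for DMM against sham at 3 days and 615 averaged, 25, 62 and 195 for sham against naive, 339 for DMM against naive at 3 days, 0 for the DMM effect between 3 days and 6 h, and 573 and 80 for operated knees; the cause was not tested.

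Scaling and filters moved fewer counts. Subtracting array medians gave 24 genes for the DMM effect between 7 days and 6 h and 2 for operated knees between 7 and 3 days. Limma-trend with robust moderation gave 17 for sham against naive at 3 days, 5 for the DMM effect between 3 days and 6 h and 2 for operated knees between 7 and 3 days, and averaging probe sets gave 7 for sham against naive at 3 days. The cause was not tested. Leaving out the 25% of genes with the lowest mean, and quantile normalization applied again, kept every count within 1.5 times. After quantile normalization 13 of the genes called for the DMM effect between 7 days and 6 h were higher and 41 lower (24.1% higher, against 10.3% on the deposited values), and for operated knees between 7 and 3 days the subtracted medians gave 1 higher and 1 lower. Quantile normalization also turned the larger direction of DMM against naive at 3 days (379 higher and 260 lower, 59.3% higher against 49.3%) and 7 days (713 and 629, 53.1% against 43.9%).

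The replicate numbers gave no clear sign of pairing. Of all pairs of groups, DMM 3 d with sham 7 d was the 1 with every same-numbered correlation over 0.1 (0.143 to 0.452). Weak correlations cannot show that the samples were unpaired. Each array correlated best with its own number between naive and sham 3 d (0.049 to 0.091) and between sham 6 h and DMM 3 d (0.059 to 0.159). With 3 arrays per group and many pairs of groups, such cases can arise by chance, which was not tested. With the replicate block, sham against naive at 7 days gave 24 genes and the DMM effect between 3 days and 6 h gave 4, and the other counts stayed within 1.5 times.

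Of 435 list tests 231 passed, 27 with an estimated correlation and 109 with fry. Of the 109, 104 were also among the 231 and had the same direction there. The estimate allows for members that move together, which widens the test by construction; for fry the cause was not tested. The correlation of DMM and sham responses ranged from 0.529 to 0.583 at 6 h, 0.593 to 0.658 at 3 days and 0.711 to 0.752 at 7 days with naive arrays left out in turn, and the highest values came without naive replicate 3.

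Among 149 values of named genes, 135 of them called, 3 changed sign in some fit, and none of the 3 was called. Col2a1 in DMM against sham at 6 h (0.01) was -0.01 with medians subtracted, 0 with the interquartile range as a covariate, -0.21 without the 4 arrays and from -0.17 to 0.21 with 1 array left out. Il6 at 6 h and Adamts5 averaged over times changed sign with 1 array left out (from -0.29 to 0.76 and from -0.03 to 0.10). Of the 135 called values, 28 lost their call with only the groups compared, 39 with the 2-fold requirement, 21 without the 4 arrays, 11 with limma-trend, 8 with the covariate, 4 with the replicate block, and 2 each with medians subtracted, probe sets averaged or quantile normalization. With the 2-fold requirement set aside, 85 of the 149 values kept their sign and call status in every fit. With 1 array left out, 178 of 1368 values lost their call, a total that also holds values with no call to lose. Signal over background was not known, so a gene of low signal that shows no change may be below what these arrays measure, and leaving out the 25% of genes with the lowest mean gave 345 calls for DMM against sham at 6 h.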

Other observations

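Further gene groups also differed between DMM and sham knees in the average over times. Of 14 adipocyte genes, 5 fell, among them Scd1 (-0.72, SE 0.15, adjusted p = 0.00682), a fatty acid desaturase, Dgat2 (-0.58, SE 0.11, adjusted p = 0.00362), which completes triglyceride synthesis, and Lpl (-0.54, SE 0.12, adjusted p = 0.0107), a lipase that frees fatty acids, and 10 fell when adjusted over the list alone (list adjusted p = 7.54e-09, but adjusted p = 0.235 with an estimated correlation). Of 13 genes of hypoxia and glycolysis, 5 rose, including Egln3 (0.73, SE 0.10, adjusted p = 0.000146), the glucose transporter Slc2a1 (0.47, SE 0.09, adjusted p = 0.0025) and Pgk1 (0.42, SE 0.07, adjusted p = 0.00111), as did 5 when adjusted over the list alone (list adjusted p = 8.4e-05, but adjusted p = 0.183 with an estimated correlation).

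Of 14 circadian clock genes, 4 fell in the same comparison, among them Dbp (-0.71, SE 0.10, adjusted p = 0.000122) and Nr1d2 (-0.37, SE 0.07, adjusted p = 0.00395), outputs and regulators of the clock, and adjusted over the list alone 9 fell and 2 rose (list adjusted p = 9.47e-05, but adjusted p = 0.13 with an estimated correlation). The hour of day at which knees were collected is not in the labels used here. The erythroid genes that fell, as counted above, included Rhd (-0.80, SE 0.16, adjusted p = 0.00356) and Alas2 (-0.53, SE 0.13, adjusted p = 0.0217). Alas2 did not pass without DMM 3 d replicate 3 or DMM 7 d replicate 1. At each time the lowest erythroid score was in the DMM array with the narrowest interquartile range of its group, -1.222 in DMM 6 h replicate 2 (3.21; -0.50 and -0.098 in replicates 1 and 3), -1.131 in DMM 3 d replicate 3 (3.18) and -0.676 in DMM 7 d replicate 1 (3.17).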
